A study of Mus musculus with 10 samples.

How the data were processed

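RNA was sequenced from left ventricular tissue of C57BL/6 mice, collected 6 weeks after transverse aortic constriction (TAC), a banding of the aortic arch that loads the left ventricle with pressure. Per the labels, 6 samples were wild type and 4 were Sirt5 knockout. The group and the number of each sample were taken from its title, and wild-type replicates are numbered 1, 3, 4, 5, 6 and 7 and knockout replicates 2, 3, 4 and 5. The series' design text describes male mice, a conventional knockout made with CRISPR-Cas9 and also a tamoxifen-inducible Cre system, and does not say which animals each description covers. It also names different ribosomal RNA removal kits and sequencing instruments, and does not assign them to samples. No label says that the samples came from separate animals, so p-values measure the spread between these samples, which may be technical in part. Sham-operated animals are mentioned in the design text and were not analysed here.

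The deposited table gives an FPKM value (fragments per kilobase of transcript, scaled to the mapped fragments of the whole library) per transcript and sample. Per the series' design text, the authors removed ribosomal RNA, made libraries in which the second cDNA strand was digested, mapped filtered reads to GRCm38 with HISAT2, whose version is not given in the sources used here, and computed FPKM with StringTie 1.2.0. HTSeq 0.6.1 read counts are mentioned in the same text and were not used here. Whether StringTie used the strand of the reads is not given in the sources used here, so reads of a transcript and of a gene on its opposite strand may not have been told apart, and StringTie shares the reads of overlapping isoforms between them by estimation. A transcript inside an intron of a host gene can also take up reads of the host's unspliced RNA.

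The table held 20741 transcripts, of which 19112 had Ensembl identifiers and 1629 had identifiers that StringTie gives to transcripts it assembled itself. The assembled transcripts carry no coordinates in the table, so their position and neighbours are not reported. Of the Ensembl identifiers, 18969 matched GENCODE release M21 on GRCm38, which supplied symbols, positions and classes, and 143 did not. Of the matched transcripts, 8519 were lincRNA, 4201 antisense, 3257 of the class that awaits experimental evidence (TEC), 2212 processed transcripts and 352 sense intronic, and 98 belonged to genes annotated as protein coding. The table is therefore one of long non-coding transcripts, and the rule by which they were chosen is not given in the sources used here. No Sirt5 transcript was in it. Of 794 genes in 48 lists fixed before the data were examined (hypertrophy, metabolism, SIRT5 substrates, stress responses and cell type markers), 1 gene, Xist, was in it, and 0 lists had the 5 members a test needed. The planned check of Sirt5 and the planned list tests could therefore not be computed, and lists of long non-coding RNA classes and families, chosen after the table was seen, were tested in their place.

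Transcript FPKM were summed per gene, which gave 14787 genes and assembled loci, 8262 of them above 0 in a sample. Of 31 genes that shared a symbol, 16 were set aside in favour of the gene with the highest mean. The 1122 genes and loci with a mean FPKM of at least 1 over all 10 samples were tested, 859 of them assembled loci and 263 Ensembl genes. Values were taken as log2(FPKM + 1), so a log2 fold change understates the change of a gene of low FPKM. Genotypes were compared with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation along an intensity trend, genotype as the only term and Benjamini-Hochberg adjustment, at an adjusted p below 0.05. All p-values are two-sided. Lists with at least 5 tested members were compared with the remaining genes by limma's camera with its preset inter-gene correlation of 0.01. Each list was tested again with an estimated correlation, with fry, and with an exact permutation test of its mean log2 value per sample. Fry and the permutation test ask whether a list changed between genotypes, without comparing it with the remaining genes. Single values were compared with an exact permutation test over all 210 splits of the 10 samples into 6 and 4, whose smallest possible p is 0.00476. Annotation was handled with pandas 2.3.3 in Python 3.11.15.

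The fit was tested on simulated data for the comparison of knockout with wild type. With 200 of 1122 genes changed, it recovered 83% of those changed by 1 on the log2 scale and 100% of those changed by 2, and 15 of its 198 calls (7.58%) were false. So many calls ease the Benjamini-Hochberg adjustment. With the 2 calls of the real data it was stricter, so these shares do not give the power of the fit there.

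Genes were named by a rule fixed before the data were examined: the 10 largest rises and 10 largest falls among annotated genes past the threshold whose genotypes did not overlap, filled up with the smallest unadjusted p in that direction where fewer passed, and leaving out predicted genes and loci without a symbol. As no annotated gene passed, all 20 genes named under that rule are genes that did not pass. The 2 loci past the threshold, 2 loci near it and a set of well-studied long non-coding RNAs were named after their values were seen.

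The depth of each library is not stated with the table, and was estimated from the values. In genes with a single transcript, FPKM multiplied by transcript length rises in steps, and the step that 1 fragment makes differed between samples. It corresponds to 22700000 to 29800000 mapped fragments per library. Between 42.6% and 48.6% of the low values lay within 0.05 of a whole number when counted in steps of 0.5 fragment, so whole reads could not be recovered and no count test was run. At these depths an FPKM of 1 in a transcript of 1 kilobase stands for 22.7 to 29.8 fragments.

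Alternatives fixed before the data were examined were other pseudocounts (0.1 and 0.5), no filter or a mean FPKM of at least 5, and 3 other scalings, namely rescaling to a common sum per sample, median-of-ratios and quantile normalization. A fit without the trend, a robust fit, array weights, an exact permutation test per gene, the replicate number as a block, leaving out each sample in turn, and summing genes with the same symbol were also fixed then. A mean FPKM of at least 0.1, a fit per transcript, principal components without Rmrp and the lists of classes and families were added after the data were seen.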

Results

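Long non-coding RNA was measured in the left ventricle of mice 6 weeks after transverse aortic constriction (TAC), which loads the left ventricle with pressure and leads to hypertrophy. The series asks what part SIRT5, a mitochondrial sirtuin that removes succinyl, malonyl and glutaryl groups from lysine, plays in restraining that hypertrophy. Animals lacking Sirt5 (4 samples) were compared with wild-type animals (6 samples), all after TAC. The table analysed here holds FPKM of long non-coding transcripts, so neither Sirt5 itself, at position 43365496 to 43395203 of chromosome 13 on GRCm38, nor the messenger RNAs of hypertrophy, metabolism or cell type could be followed. The genotype labels therefore could not be checked against the targeted gene. Xist, the long non-coding RNA of the inactive X chromosome, lay between 0 and 0.0226 FPKM in the 10 samples, as in males.

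The libraries held an estimated 22700000 to 29800000 mapped fragments. Wild-type libraries were deeper on average (26700000 ± 2010000, SD, n = 6) than knockout libraries (24100000 ± 1300000, SD, n = 4), with an exact permutation p of 0.0571. A large part of the table came from 2 loci, Gm26917 and Gm42418, that lie next to each other on chromosome 17 (39843013 to 39846341 and 39846958 to 39848788) at a copy of the ribosomal RNA precursor. Together they took 42.8 ± 6.19% of the summed FPKM in wild type (SD, n = 6) and 48.6 ± 2.41% in knockout (SD, n = 4; exact permutation p = 0.114).

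Loss of Sirt5 went with few detectable changes among long non-coding RNAs of the pressure-loaded ventricle. The assembled locus MSTRG.35125, with 3 transcripts, fell from 6.93 ± 2.14 FPKM in wild type (SD, n = 6) to 0.744 ± 0.889 FPKM in knockout (SD, n = 4), a log2 fold change of -2.26 (SE 0.292, limma adjusted p = 0.0101). Its lowest wild-type sample had 4.38 FPKM and its highest knockout sample, replicate 5, had 2.06. The assembled locus MSTRG.13051 rose from 1.00 ± 0.160 to 2.14 ± 0.376 FPKM (SD, n = 6 and n = 4; log2 fold change 0.65, SE 0.106, limma adjusted p = 0.0423). These were the only calls among 1122 genes and loci, 1 in each direction. Of the called loci, MSTRG.35125 alone changed at least 2-fold on the log2(FPKM + 1) scale. That scale understates changes of low loci (the log2 fold change of MSTRG.13051 was 1.02 with a pseudocount of 0.1). Neither has a position in the table, so what they overlap is unknown here. MSTRG.35125 missed the threshold without knockout replicate 2 (limma adjusted p = 0.0561), and MSTRG.13051 missed it when any one of the 10 samples was left out (limma adjusted p from 0.0561 to 0.121). Both also missed it with no filter (limma adjusted p of 0.124 and 0.227) and after rescaling to a common sum per sample (0.0635 and 0.177), and MSTRG.13051 did so without the trend (0.0529) and at a mean FPKM of at least 0.1 (0.132). The exact permutation test per locus gave an adjusted p of 0.191 for each. Both had the smallest unadjusted p that this test can give, 0.00476, so no larger difference at either locus could have lowered it.

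**Figure D1:**
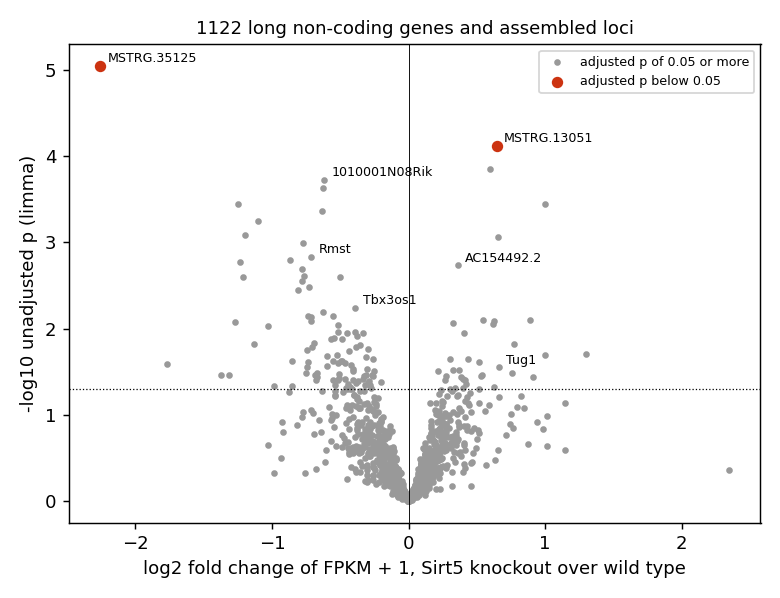
Log2 fold change of FPKM + 1, Sirt5 knockout over wild type, on the horizontal axis and significance (-log10 of the unadjusted limma p) on the vertical axis. Each of the 1122 points is a long non-coding gene or assembled locus, and the dotted line marks an unadjusted 0.05. The 2 red points are the loci past an adjusted p of 0.05, and more of the points above the dotted line lie on the left (96) than on the right (35).

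At an unadjusted p below 0.05, 96 loci were lower in knockout and 35 higher, so 73.3% of them were lower. The balance moved with the scaling: the split was 74 lower to 47 higher after quantile normalization, 85 to 45 with median-of-ratios scaling and 142 to 9 after rescaling to a common sum per sample, where the median log2 fold change of all loci was -0.22 against -0.03 as deposited. That rescaling divides by the table sum, 8117 ± 1053 FPKM in wild type and 9112 ± 434 FPKM in knockout (SD, n = 6 and n = 4). Gm26917 and Gm42418 held much of it, with means of 2789 and 714 FPKM in wild type and 3403 and 1025 FPKM in knockout. A higher sum in knockout lowers the rescaled values of its other loci. With no filter on low values the split was 209 lower to 220 higher. Without knockout replicate 5 it was 66 to 32, and without knockout replicate 2 it was 65 to 48. The genotypes did not overlap in 36 of the 1122 loci (3.21%), 24 lower and 12 higher, where chance gives 0.952% of loci.

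The annotated gene nearest the threshold, picked after its values were seen, was 1010001N08Rik (ENSMUSG00000097222.2, chromosome 18, 10987944 to 11052567, minus strand), which overlaps Gata6, a transcription factor of the heart, on the opposite strand. Its FPKM was 2.36 ± 0.234 in wild type (SD, n = 6) and 1.20 ± 0.313 in knockout (SD, n = 4), a log2 fold change of -0.62 (SE 0.113) with a limma adjusted p of 0.0521, and every knockout sample lay below every wild-type sample. With a robust fit its adjusted p was 0.0461 and with array weights 0.0286, within a range of 0.0286 to 0.505 over 23 alternatives. Tbx3os1 (chromosome 5, 119570130 to 119671365, minus strand) runs opposite Tbx3, a transcription factor of the conduction system. It had 1.91 ± 0.340 FPKM in wild type and 1.22 ± 0.221 FPKM in knockout (SD, n = 6 and n = 4), again without overlap (log2 fold change -0.39, SE 0.114, limma adjusted p = 0.268). Hand2os1, opposite Hand2, had 24.1 ± 5.16 FPKM in wild type and 19.4 ± 2.90 FPKM in knockout (SD, n = 6 and n = 4), a difference within the spread between samples (limma adjusted p = 0.680), and its log2 fold change went from -0.29 to -0.18 without knockout replicate 5. Reads of these transcripts and of their partners on the opposite strand may not have been told apart.

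**Figure D2:**
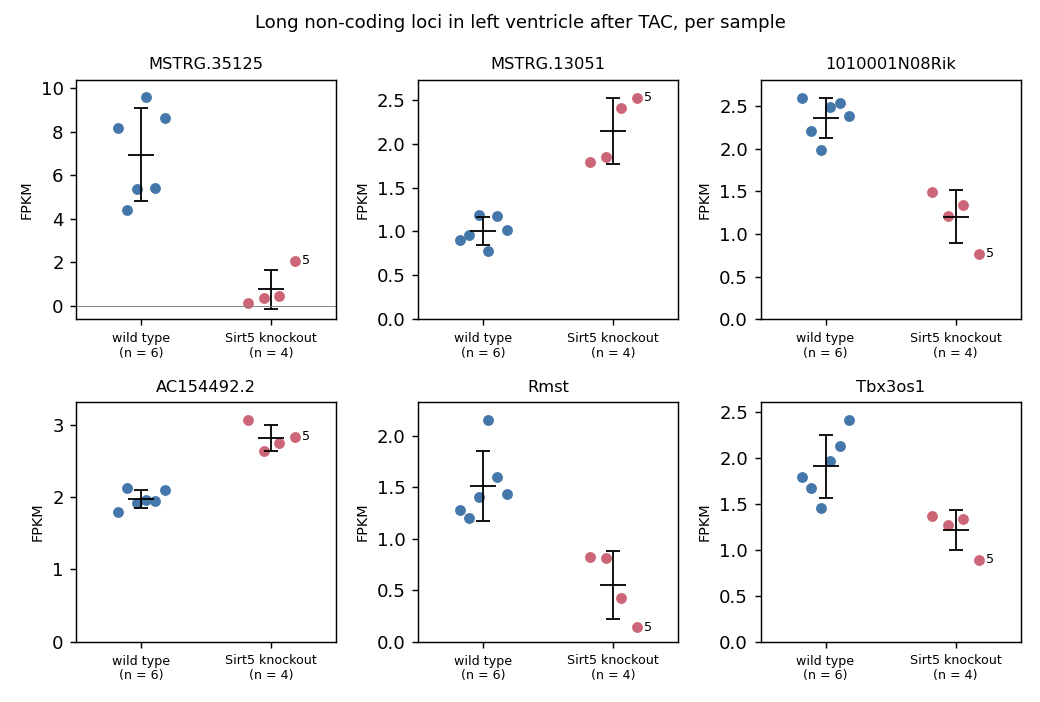
FPKM (vertical axes, from 0 or just below) of 6 long non-coding loci in 6 wild-type and 4 Sirt5 knockout samples; each point is a sample, bars are the mean and SD, and 5 marks knockout replicate 5. The genotypes do not overlap in any of the 6 loci, of which MSTRG.35125 and MSTRG.13051 passed an adjusted p of 0.05.

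Among the other annotated transcripts that the naming rule picked, Rmst and AC154492.2 also separated the genotypes. Rmst, a lincRNA on chromosome 10 (92071037 to 92165170, minus strand), had 1.51 ± 0.342 FPKM in wild type and 0.552 ± 0.331 FPKM in knockout (SD, n = 6 and n = 4; log2 fold change -0.71, SE 0.169, limma adjusted p = 0.127). AC154492.2 lies in an intron of Rhoq, a small GTPase gene, on the same strand (chromosome 17, 86970372 to 86975288, plus strand). It had 1.97 ± 0.125 FPKM in wild type and 2.82 ± 0.180 FPKM in knockout (SD, n = 6 and n = 4), a log2 fold change of 0.36 (SE 0.0890, limma adjusted p = 0.129), and part of it may be unspliced Rhoq RNA. AC158975.2, a lincRNA on chromosome 18, lay between 4.88 and 5.57 FPKM in wild type and at 4.67, 3.66, 1.52 and 0 FPKM in knockout replicates 2, 3, 4 and 5 (limma adjusted p = 0.343). ENSMUST00000238681, which GENCODE M21 does not list, lay between 1.46 and 3.53 FPKM in wild type and at 0, 0, 0.879 and 0.702 FPKM in the same order of knockout replicates (limma adjusted p = 0.0572). It passed with array weights alone (limma adjusted p = 0.0361), within a range of 0.0361 to 0.550 over 23 alternatives.

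The remaining named genes overlapped between genotypes, and none had a limma adjusted p below 0.393. Higher means in knockout were seen for Tug1 (3.67 ± 1.55 against 6.28 ± 2.05 FPKM), Spata5l1 (1.55 ± 0.426 against 2.17 ± 0.312 FPKM), Tctn2 (1.25 ± 0.177 against 1.73 ± 0.436 FPKM) and Pvt1, the neighbour of Myc (1.34 ± 0.196 against 1.92 ± 0.926 FPKM; all SD, n = 6 and n = 4). The means of Snhg17, Snhg20, Neat1 and Ifi30 were higher as well. Lower means were seen for Epb41l4aos (1.98 ± 0.763 against 1.03 ± 0.320 FPKM), Ndufb1-ps (4.31 ± 1.23 against 2.88 ± 0.442 FPKM), AC120164.1 (1.60 ± 0.419 against 1.06 ± 0.508 FPKM) and Tmem147os (1.28 ± 0.199 against 0.937 ± 0.308 FPKM; all SD, n = 6 and n = 4). AU023070, inside Corin, the gene of the protease that activates natriuretic peptides, had 5.21 ± 1.75 FPKM in wild type and 2.78 ± 1.40 FPKM in knockout (SD, n = 6 and n = 4). AC158549.1, which lies 7916 bases from the adrenergic receptor gene Adrb1, had 3.98 ± 1.36 and 2.48 ± 1.36 FPKM (SD, n = 6 and n = 4). Several of these differences rest on knockout replicate 5: without it the log2 fold change went from 0.27 to 0.07 for Pvt1, from 0.27 to 0.17 for Tctn2, from 0.74 to 0.12 for Ifi30, from 0.45 to 0.20 for Snhg17, from -0.59 to -0.25 for AC158549.1, from -0.36 to -0.16 for AC120164.1 and from -1.13 to -0.63 for AC158975.2. Without knockout replicate 2 that of Tmem147os went from -0.24 to -0.15, and that of Neat1 went from 0.94 to 1.42 without knockout replicate 3 and to 0.31 without knockout replicate 5.

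Long non-coding RNAs known from heart and vessel showed no shared direction. Of 16 tested, 8 had a higher and 8 a lower fold change and 0 passed (limma, with 1 higher and 2 lower at an unadjusted p below 0.05), and the list had a camera adjusted p of 0.798, with a median log2 fold change of -0.02 and a mean of 0.10. Without knockout replicate 5, 6 of 15 were higher, with a median and a mean of -0.06 each (camera adjusted p = 0.708). Carmn, a transcript of smooth muscle cells, had 13.8 ± 2.41 FPKM in wild type and 10.2 ± 1.52 FPKM in knockout (SD, n = 6 and n = 4; limma adjusted p = 0.499). Bvht, which is known from cardiac lineage commitment but was not on the list, lies on the other strand next to Carmn on chromosome 18. It had 1.25 ± 0.267 and 1.71 ± 0.271 FPKM (SD, n = 6 and n = 4). Its log2 fold change was 0.27 (limma unadjusted p = 0.0357, adjusted p = 0.404), and the counts above leave it out. Mhrt, antisense to the myosin heavy chain gene Myh7, had 3.25 ± 1.48 and 2.81 ± 1.56 FPKM (SD, n = 6 and n = 4; limma adjusted p = 0.855). Its log2 fold change of -0.19 turned to 0.12 without knockout replicate 5. Gas5 had 9.06 ± 1.95 and 8.86 ± 2.96 FPKM (SD, n = 6 and n = 4; limma adjusted p = 0.965), and its log2 fold change went from -0.05 to -0.24 without that library.

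Host genes of small nucleolar RNAs were the only family past camera. Of 9 tested, 8 had a higher fold change in knockout, under the deposited scaling and the 3 other scalings alike, with a median log2 fold change of 0.25 (camera adjusted p = 0.0395), and 0 passed singly (limma, 0 at an unadjusted p below 0.05). With an estimated correlation the adjusted p was 0.538, and without knockout replicate 5 it was 0.690 with the preset correlation, with 7 of 9 higher and a median of 0.06. Snhg17 had 1.12 ± 0.238 FPKM in wild type and 2.06 ± 1.27 FPKM in knockout, and Snhg20 had 3.41 ± 1.87 and 5.12 ± 0.416 FPKM (SD, n = 6 and n = 4). Snhg17 reached 3.86 FPKM in knockout replicate 5 and lay between 0.806 and 2.02 FPKM in the other 9 samples.

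No class of transcript passed camera. The antisense class, with 43 of 56 members lower and a median log2 fold change of -0.19, had an adjusted p of 0.119, and its median was below 0 under the 3 other scalings too. Without knockout replicate 5, 33 of 55 were lower, with a median of -0.05 and an adjusted p of 0.708. The processed transcript class, with 50 of 80 members higher, also had an adjusted p of 0.119, and its median of 0.08 was -0.07 after rescaling to a common sum per sample. Without knockout replicate 5, 41 of 77 were higher, with a median of 0.03 and an adjusted p of 0.690. Adjusted p was 0.414 for transcripts at bidirectional promoters, 0.692 for transcripts named as opposite-strand, 0.798 for lincRNA, 0.798 for the class awaiting experimental evidence (median -0.08 and mean -0.10, with a test direction towards higher), 0.993 for sense intronic transcripts and 0.993 for assembled loci. Host genes of microRNAs and imprinted long non-coding RNAs reached 5 members only at a mean FPKM of at least 0.1, with adjusted p of 0.853 and 0.272.

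Knockout replicate 5 stood apart from the other 9 samples. Malat1, a nuclear RNA, stood at 951 FPKM in that library and between 58.4 and 81.8 FPKM in the other 9. Neat1, the scaffold of paraspeckles, was at 9.02 FPKM against 3.08 FPKM in knockout replicate 4 and at most 0.756 FPKM in wild type, and Ifi30, the gene of a lysosomal reductase, at 21.4 FPKM against at most 4.27 FPKM. Dnm3os, a host of microRNAs, was at 4.65 FPKM against at most 0.827 FPKM, and the imprinted H19 and Meg3 were at 4.21 and 7.92 FPKM against at most 1.92 and 3.76 FPKM. AC132253.9, a lincRNA on chromosome 19, was at 9.19 FPKM against 86.0 to 128 FPKM. Genotype means of these genes rest on that library: the log2 fold change of Malat1 was 0.88 (SE 0.674, limma adjusted p = 0.669) with it and -0.06 without it.

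**Figure D3:**
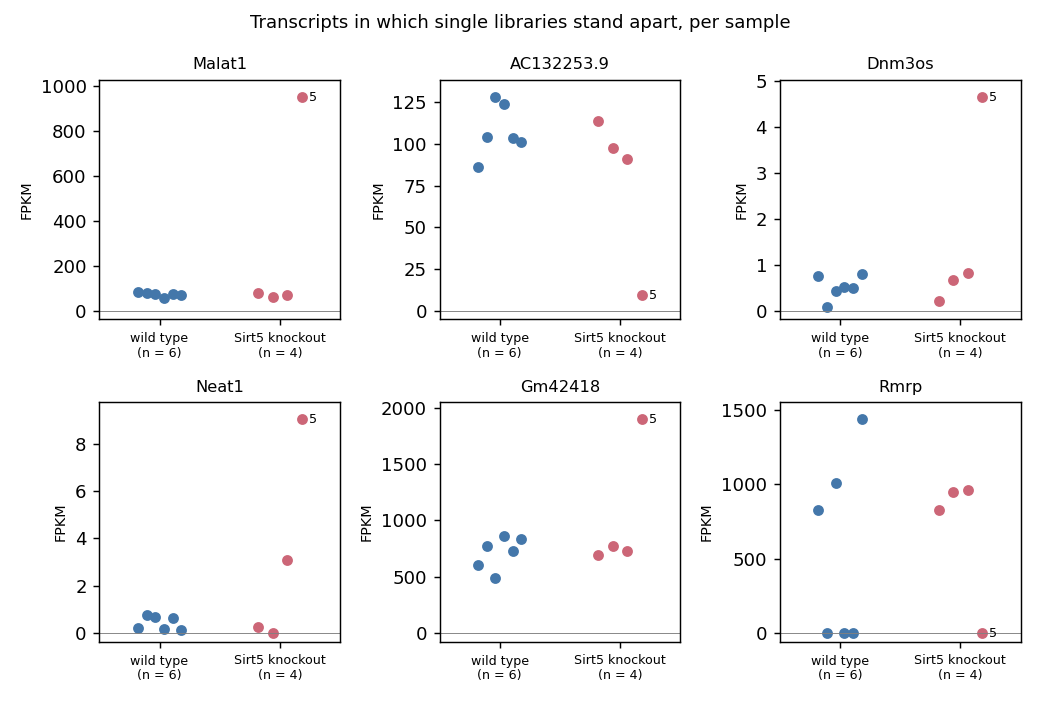
FPKM (vertical axes) of 6 transcripts in 6 wild-type and 4 Sirt5 knockout samples, each point a sample, with knockout replicate 5 marked 5. That library is apart from the other 9 in Malat1 (951 FPKM), AC132253.9 (9.19 FPKM) and Dnm3os (4.65 FPKM), and Rmrp is listed at 0 in it and in 3 wild-type libraries.

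Across the 1122 loci, the correlation of log2 values between pairs of samples was 0.520 to 0.618 for pairs with knockout replicate 5 and 0.655 to 0.824 for pairs without it; these are correlations across genes, which are not independent replicates. The first principal component held 25.2% of the variance, with a score of 20.3 for knockout replicate 5 and scores of -6.51 to 2.96 for the other 9, and did not separate the genotypes (exact permutation p = 0.338). The second held 19.9% (exact permutation p = 0.0571) and the third 10.6% (exact permutation p = 0.771). On the second, wild-type replicates 3, 5 and 6 scored 8.57 to 10.1 and wild-type replicates 1, 4 and 7 scored -6.23 to 0.84. The knockout samples scored -6.75 to -3.89, so the second component also split the wild type. Rmrp, the RNA of the RNase MRP complex (chromosome 4, 43492783 to 43493063, minus strand), had the largest weight on the first and second. It was listed at 0 in wild-type replicates 3, 5 and 6 and knockout replicate 5, at 824, 1011 and 1434 FPKM in wild-type replicates 1, 4 and 7, and at 827, 948 and 963 FPKM in knockout replicates 2, 3 and 4. Without Rmrp, the first component had a knockout mean of 5.34 and a wild-type mean of -3.56 (exact permutation p = 0.00952), with a score of 19.7 for knockout replicate 5.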

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

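The tests of short transcripts, of the share in the more frequent direction and of loci without overlap in other splits were set before their results were seen; the other tests named here were chosen after the pattern was seen. Samples were set against the others of their genotype in 84 groups of values, of which 10 had a sample farther out than Dixon's test allows at 95%. Chance would give about 1 in 20 groups, or 4.2, for values chosen without sight of the data. Some of these values were named after they were seen, so the count of 10 is no test of chance. Of the 10, 6 were in knockout replicate 5.

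In that library Malat1 stood at 951 FPKM (59.8 to 78.9 in the other 3 knockout samples), Gm42418 at 1895 FPKM (697 to 777), Ifi30 at 21.4 FPKM (2.38 to 4.27), Dnm3os at 4.65 FPKM (0.206 to 0.827), H19 at 4.21 FPKM (1.32 to 1.67), and Rmrp was listed at 0 FPKM (827 to 963). In the other libraries, Carmn was at 12.5 FPKM in knockout replicate 3 (9.42 to 9.56 in the others), Meg3 at 0.517 FPKM in wild-type replicate 5 (2.13 to 2.99), and Xist at 0.0226 FPKM in wild-type replicate 7 (0 to 0.00750), near the floor. The ratio of Gm26917 to Gm42418 was 2.28 in wild-type replicate 6 and 3.96 to 4.92 in the other wild-type samples.

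Knockout replicate 5 was the highest or lowest of the 10 samples by at least 1 on the log2 scale in 30 of the 1122 loci, against 0 to 5 loci for each of the other 9. Low depth is argued against: the library with the fewest fragments is knockout replicate 4, at 22700000 against 23700000, and its median correlation with the other samples was 0.774 against 0.574. A general rise of intronic RNA is argued against as well, since the 18 sense-intronic genes had a median log2 ratio of 0.10 to the other 9 samples (quartiles -0.05 and 0.28) and the Malat1 ratio was 12.9-fold. A rise of RNA kept in the nucleus stays open, with ratios of 12.9 for Malat1, 32.8 for Neat1 and 2.31 for Firre but 0.615 for Kcnq1ot1. A different yield of ribosomal RNA fragments, from library preparation or RNA integrity, stays open: the ratio of Gm26917 to Gm42418 was 1.32 there and 2.28 to 5.58 in the other 9, which may or may not share a cause with Malat1. A different mix of cell types cannot be told apart from this, as 0 of the 48 fixed lists had enough members in the table, and a biological explanation was not tested. The other 3 knockout samples lay near the wild type in Malat1, AC132253.9 and Dnm3os, but Neat1 was also higher in knockout replicate 4 (3.08 FPKM) than in any wild-type sample (at most 0.756 FPKM).

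Rmrp was listed at 0 in 4 of the 10 libraries. Sampling is argued against, since the 6 libraries with a value above 0 each hold at least about 5998 fragments of it. Loss of short RNA is argued against, because the 11 other transcripts under 350 bases had a median log2 difference of 0.0010 between these 4 libraries and the other 6 (quartiles -0.07 and 0.11). Genotype as the whole cause is argued against, with 3 wild-type and 1 knockout libraries at 0 (Fisher's exact test, two-sided p = 0.571). Rmrp was the only transcript above 1 FPKM that was at 0 in these 4 libraries and above 0 in the other 6, so a failed estimate at this locus may be involved, which was not tested.

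The lean towards lower values in knockout (96 loci against 35 at an unadjusted p below 0.05, a share of 73.3%) was set against other splits of the samples. Of 100 of the 210 splits into 6 and 4, 16 gave as large a share in the more frequent direction, the real one included, and the highest other gave 90.2%, so chance is not excluded. The share was 67.3% without knockout replicate 5, 57.5% without knockout replicate 2 and 48.7% with no filter on low values. It was 61.2% after quantile normalization and 94.0% after rescaling to a common sum. That rescaling divides by a table sum that was higher on average in knockout, and it also lowered the weight of the pseudocount. Whether replicate 5 or the scaling accounts for part of the lean stays open.

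For the 2 loci past the adjusted threshold, 3 of the 100 splits gave as many, with 3 loci in the highest other. For the 131 loci at an unadjusted p below 0.05, 2 splits gave as many, with 136 in the highest other, and for the 36 loci without overlap 2 splits did, with 40 in the highest other. Each share was below 0.05, but only 100 of the 210 possible splits were drawn, and the 3 counts are not independent. The tests of the first 2 counts were chosen after the pattern was seen, so chance is not excluded. The split with 136 and 40 set wild-type replicates 3, 4, 5 and 6 against the other 6 samples, which include all 4 knockout samples.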

How the results depend on the processing

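The mean FPKM of at least 0.1, the principal components without Rmrp and all list tests were chosen after seeing the data. Across the 24 loci past or near the threshold or named by the rule, 408 refits gave a fold change other than the main one, and all 408 kept its direction. These loci were picked for their differences in the same samples, and each refit reused all or most of those samples. The kept direction is therefore no independent test. The other well-studied RNAs were refitted only without knockout replicate 5, where Mhrt (-0.19 to 0.12), Malat1 (0.88 to -0.06) and Mir22hg (0.02 to -0.16) changed direction. The counts that follow are of loci at an adjusted p below 0.05, except where an unadjusted p is named. The count of loci higher in knockout was 1, and became 0 with no filter, a mean FPKM of at least 5 (58 loci tested), rescaling to a common sum, no trend, the exact permutation test per gene and a mean FPKM of at least 0.1. It became 2 with a pseudocount of 0.5, quantile normalization and a robust fit, and 3 with array weights. The count of lower loci was 1, and became 0 with no filter, a mean of at least 5, rescaling and the permutation test, 2 with a pseudocount of 0.1 or 0.5 or quantile normalization, 3 with a robust fit and 5 with array weights. The count of 2-fold changes was 1, and became 0 with no filter, a mean of at least 5, rescaling and the permutation test, 3 with a pseudocount of 0.1 and 4 with array weights. Without a filter, 220 loci were higher and 209 lower at an unadjusted p below 0.05, with the permutation test 42 and 85, and after rescaling 9 and 142. Leaving out 1 sample at a time gave 0 to 1 higher, 0 to 2 lower and 0 to 2 changed 2-fold, and 0 in each without knockout replicate 2 (48 higher and 65 lower at an unadjusted p below 0.05). The higher locus found without wild-type replicate 1, and that found without knockout replicate 5, was not MSTRG.13051 (limma adjusted p of 0.0593 and 0.0917 there). No filter adds low loci to the adjustment, a mean of at least 5 leaves out both called loci, and the permutation test cannot go below 0.00476 per locus; the cause of the other changes was not tested.

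Whether same-numbered samples pair cannot be told from 3 such pairs. Their deviations correlated at -0.163 (replicates 3), 0.176 (replicates 4) and 0.0807 (replicates 5). Differently numbered pairs ranged from -0.221 to 0.252. With the replicate block, 0 loci were higher, 0 lower and 0 changed 2-fold at an adjusted p below 0.05. At an unadjusted p below 0.05, 39 were higher and 64 lower. The limma adjusted p with the block was 0.201 for MSTRG.35125 and 0.421 for MSTRG.13051.

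The second principal component had an exact permutation p of 0.0571, and 0.0429 over the 500 loci with the highest variance. With a sample left out, the second had from 0.0397 (without wild-type replicate 1) to 0.417 (without knockout replicate 5). Without Rmrp the first had 0.00952, with knockout replicate 5 at a score of 19.7 and the other 9 samples between -5.52 and 1.42. Components were computed anew in each setting and matched by rank only, so the second without knockout replicate 5 may be a different axis. The count of lists past camera was 1, and became 0 with an estimated correlation, at a mean of at least 0.1 and without knockout replicate 5. Fry and the permutation test of the list mean, which do not compare a list with the remaining genes, passed 0 lists. Sirt5 and the fixed lists gave no value under any setting, as the table holds no Sirt5 transcript and 1 of the 794 listed genes. Depth limits low loci: at an FPKM of 1, a transcript of 1 kilobase has 22.7 to 29.8 fragments.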

Other observations

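Within 1 megabase of Sirt5 on chromosome 13, 2 long non-coding genes had a mean FPKM of at least 0.1. Gm47781 (44232398 to 44239606) lay at 0, 1.03, 0.371, 0.735, 0.571 and 0.191 FPKM in wild-type replicates 1, 3, 4, 5, 6 and 7, and at 0.119, 0.169, 0.0268 and 0.0358 FPKM in knockout replicates 2, 3, 4 and 5. Gm33195 (43864669 to 43868589) lay between 0.129 and 0.294 FPKM in wild type and between 0.0405 and 0.155 FPKM in knockout.

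Other transcripts set knockout replicate 5 apart. C130080G10Rik was at 2.28 FPKM there and at 3.54 to 38.1 FPKM in the other 9 samples, and Gm45670 at 1.02 against 6.05 to 18.9 FPKM. Gm12840 was at 15.3 FPKM against 1.03 to 4.98, Gm12295 at 8.68 against 0.189 to 2.65, Firre, a nuclear RNA of the X chromosome, at 8.27 against 2.10 to 4.43, and Snhg1 at 9.30 against 3.09 to 4.88 FPKM. The 56 antisense genes had a median log2 ratio of -0.38 to the other 9 samples in this library, the 80 processed transcripts 0.11 and the 80 lincRNA -0.21. Mhrt was at 0.835 FPKM there and at 1.22 to 5.78 FPKM in the other 9.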
